A study of Homo sapiens with 4 samples.

How the data were processed

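HK-2 is an immortalised human proximal tubular epithelial cell line. Per the labels, cells were left untreated or given 10 ng/ml TGF-β1, a cytokine that drives fibrotic responses, for 24 h, and chromatin was fixed, digested with micrococcal nuclease and sonicated before immunoprecipitation with an antibody to FOXK1, a forkhead transcription factor. Each condition had 1 FOXK1 library and 1 input library, so the series held 4 libraries and no replicates. The labels gave each library its group.

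The deposited measurement was a list of peaks for each condition, with a chromosome, a start, an end and a signal per peak, which was the authors' pileup height in whole numbers of at least 3. Peaks were listed separately for the untreated and the TGF-β1 library and were not pooled. Per the submitters' processing notes, bcl2fastq 2.17 and MACS2 2.1.1.20160309 were used with the hg38 genome. The aligner, the read filters, the peak threshold and the number of reads per library were not given in the sources used here. Sequencing depth is therefore unknown, and the number and height of peaks both move with depth. For that reason the height was used to describe, rank or filter the peaks of each list, and heights printed for both lists side by side are not a measure of change. Some minimum heights were the same for both lists. At unknown depth the same minimum need not be equally strict in each, so counts and shares above it are not a measure of change either. The height given for a gene is that of its highest gene-end peak in each list, and these peaks need not overlap. A gene in 1 list only had no gene-end peak in the other list, which may still hold a peak just beyond the window.

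Peaks on the 24 assembled chromosomes were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The lists held 0 exact duplicates and 0 overlaps within a list. The files did not state whether starts count from 0 or from 1. They were read as counting from 0, so that a printed start may be off by 1 bp. Gene positions came from a table of RefSeq genes on GRCh38.p14, the same chromosome coordinates as hg38, with 20033 protein-coding genes. Strand, exons and genome sequence were not used here, so a peak was assigned to a gene when it overlapped the 1 kb on either side of either annotated end of the gene, called a gene-end peak. A gene end may be a transcription start or a transcription end. The share of peaks at gene ends was counted from peak midpoints, since the lists held no summit.

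Overlap between the lists was counted at a minimum of 1 bp. Chance overlap was the mean of 100 random placements of the other list on the same chromosomes, within 1 Mb bins that held peaks, and a local chance value came from shifting the other list by 20 kb. The share of truly common peaks was estimated from the overlap and its chance value. On simulated lists made from these peak numbers with 20% and 50% common peaks, the estimate gave 19.95% and 50.04%, and with 0% it gave 0.0064%. Simulated peaks that were not common were placed at random, as for the chance value, so clustering of real peaks was not checked. Strong peaks were defined as those down to the height of the 10000th highest peak with ties kept, which gave 11072 control peaks of height 17 or more and 11342 TGF-β1 peaks of height 15 or more, lists of nearly equal length. Shares have exact binomial 95% intervals, which cover counting error only. With 1 library per condition there was no test of TGF-β1 and no p-value.

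Gene lists, named genes, comparisons and alternative settings were fixed before the data were examined. The 284 listed genes, of which 283 matched by symbol and 1 by an older symbol, formed 14 lists, and 392 olfactory receptor genes formed the 15th. The count of members with a peak was set against 10000 random lists of the same size drawn from the same 10 classes of gene length. This is a description of these libraries. Expression and promoter CpG content of the listed genes were not matched, so a high count need not be particular to their pathway. On 20033 simulated genes, 1.0% of 200 lists of 20 genes without enrichment had under 5% of random lists as high. For simulated lists at 90% occupancy it was 100%. The other simulated genes were occupied less often than the 75.3% and 74.6% of genes with a peak of any height here. The 100% therefore does not carry over to counts of peaks of any height. The genes named were the 10 with the highest gene-end peak in each list, the 10 highest found in 1 list only, 12 fixed genes, up to 8 glycolysis genes highest in the TGF-β1 list and up to 4 of every other list. A few others are named with a statement that they were chosen later, and a few that the rule takes are not reported here.

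Several planned steps had to be replaced because of what the lists hold. Promoters became gene ends, summits became midpoints, fold enrichment became pileup height, and matching on promoter CpG content became matching on gene length. Forkhead and other motifs were not analysed here. Of 48 alternative settings fixed beforehand, 8 could be run as written, and 40 that needed fold enrichment, a q value, strand or sequence were not run. In their place, heights of at least 10 and 20, strong peaks, a window of 500 bp and a peak within 5 kb of the gene were chosen after seeing the data. The definition of strong peaks was also settled then, because a fixed number of peaks split ties by position. Peaks on unplaced contigs were left out of the comparisons.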

Results

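FOXK1 was mapped by chromatin immunoprecipitation and sequencing in HK-2 proximal tubular cells with and without 24 h of 10 ng/ml TGF-β1. The series asked how FOXK1 relates to glycolysis and renal fibrosis, and the design compares FOXK1 peaks between the 2 conditions, each with 1 FOXK1 library and 1 input. The control list held 381700 peaks on assembled chromosomes covering 169.3 Mb, and the TGF-β1 list held 439136 covering 186.4 Mb. Both had a median pileup height of 5, and heights up to 7 made up 81.9% and 87.3% of the peaks. Among peaks of height 10 or more the order was the other way round, 36862 in the control list and 29466 in the TGF-β1 list. Depth was unknown and there were no replicates, so every difference below compares 2 libraries and not 2 conditions.

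The highest gene-end peaks were mostly at the same genes in both lists. The highest of all was at FBXO32, a ubiquitin ligase subunit of muscle atrophy, with heights of 414 in the control list and 455 in the TGF-β1 list; the control peak covered 123540925 to 123542030 on chromosome 8 (hg38), across the higher-coordinate end of the gene. H1-10, a linker histone, had 304 and 295, and HBP1, an HMG-box transcription factor, had 297 and 270. A peak shared by CCNE2, cyclin E2, and NDUFAF6, a complex I assembly factor, had heights of 282 and 331. WEE1, the kinase that restrains CDK1, had 191 and 193, and a peak shared by MCM7, a subunit of the replicative helicase, and AP4M1 had 188 and 215. BAHCC1 had 229 and 232, and CEBPB, a bZIP transcription factor, had 228 and 212. ETV5, an ETS transcription factor with 235 and 161, was in the first 10 of the control list.

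Overlap between the lists depended on peak height. Of control peaks, 26.1% (95% interval 26.0 to 26.2) overlapped a TGF-β1 peak, against 12.1% by random placement and 14.7% after a 20 kb shift. Of TGF-β1 peaks, 22.9% (22.7 to 22.99) overlapped a control peak, against 10.7% and 12.8%. The estimated share of common peaks was 17.5% and 15.4% with random placement as chance, and 15.2% and 13.4% with the 20 kb shift. Control peaks of height 3 overlapped in 10.6% of cases, close to their chance value of 10.1%, those of height 10 to 14 in 75.2% and those of height 20 to 29 in 96.0%. The TGF-β1 list gave 10.0%, 79.2% and 95.1% at these heights. Among strong peaks, 65.4% of control peaks overlapped a strong TGF-β1 peak and 63.9% the other way round, against 0.88% and 0.86% by chance, and 95.4% and 93.5% overlapped some peak of the other list.

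**Figure D1:**
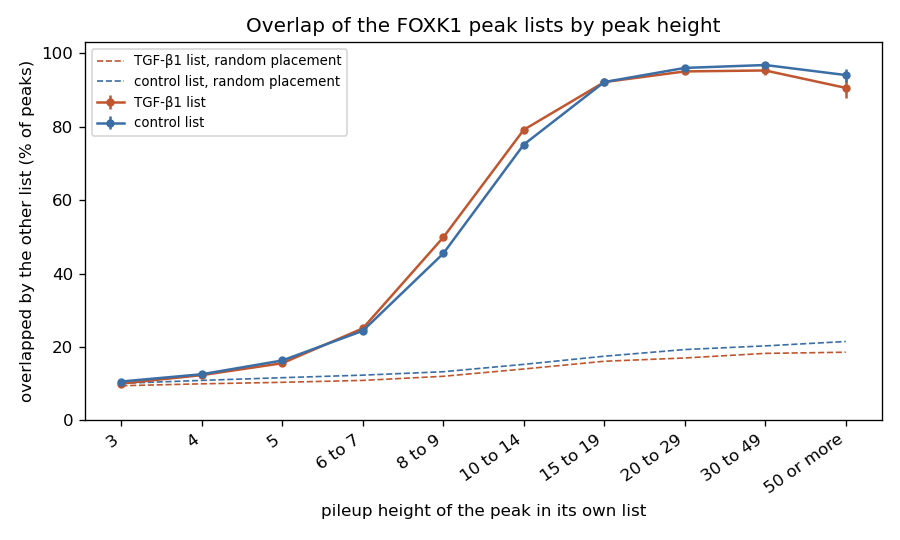
Percent of peaks overlapped by the other list (y axis) against pileup height in the peak's own list (x axis), for the control and TGF-β1 lists; points have exact binomial 95% intervals and dashed lines show the mean of 100 random placements. Overlap lay near chance at height 3 (10.6% and 10.0%) and reached 96.0% and 95.1% at heights of 20 to 29.

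Peaks were enriched at the ends of protein-coding genes, most of all the high ones. Midpoints within 1 kb of a gene end made up 4.98% of control peaks (4.91 to 5.05) and 4.44% of TGF-β1 peaks (4.38 to 4.499), against 2.50% and 2.46% by random placement. At heights of 20 or more the shares were 24.2% and 21.6%. A gene-end peak was found for 15089 of 20033 protein-coding genes in the control list and 14941 in the TGF-β1 list, against 9334 and 10122 by random placement. Both lists had 12828 of these genes, 2261 were in the control list only and 2113 in the TGF-β1 list only, and independent lists of these sizes would share 11254. For strong peaks, whose definition was settled after the data were seen, the counts were 3412 and 3145 genes, of which 2390 were common, against 536 for independent lists. Strong peaks lay at both ends of 1.94% and 1.83% of the occupied genes longer than 4000 bp.

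Few genes had a high gene-end peak in 1 list and none in the other. A strong gene-end peak in the TGF-β1 list and no gene-end peak in the control list was found for 16 genes, and the reverse for 19. For 8 of the 16 and 7 of the 19, a peak of the other list overlapped the strong peak itself and only missed the 1 kb window, so these are not sites of a single list. Without overlap in the control list were the TGF-β1 peaks of TEX19, with a height of 22, USP17L30 with 25, TAF11L9 with 21 and NBPF19 with 18. The last 3 belong to families of near-identical copies and are uncertain. Overlapped by a control peak were those of EFCAB12 and LOC107984936, each with 30, TMEM132A with 27, ZCCHC14 with 24 and MIURF with 20. Without overlap in the TGF-β1 list were the control peaks of CYSLTR2, a leukotriene receptor, with 45, PAXBP1 with 41, ZNF703 with 37, ELMOD1 and LOC101929627 with 26, and USP17L17, another near-identical copy, with 22. Overlapped by a TGF-β1 peak were those of SLC35D1, a nucleotide sugar transporter, with 29, SNTB1 and TEDDM1 with 23, and MYLK2 with 22. The LOC101929627 peak lay on chromosome 8 among other peaks of height 20 or more, of both lists, that had no counterpart, so it is uncertain too. The genes with a strong gene-end peak in 1 list only did not form a fixed list and no theme was tested among them.

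Nearly all genes of glycolysis had a gene-end peak with and without TGF-β1. The count was 22 of 24 in each list, and 21 were common. PFKL, the liver phosphofructokinase, had a gene-end peak in the TGF-β1 list only (height 7), ENO2, neuronal enolase, in the control list only (height 6), and PFKP, the platelet phosphofructokinase, in neither. Of random lists, 8.12% and 5.67% had as many members with a peak, in the control and TGF-β1 lists, and 4.04% and 3.43% when they were not matched on gene length. SLC16A1, a lactate transporter, had the highest TGF-β1 peak of the list, with heights of 34 in control and 29 in TGF-β1, and was the 1 gene strong in both. The lactate exporter SLC16A3 (15 and 26), the glucose transporter SLC2A1 (14 and 17) and the aldolase ALDOA (7 and 15) were strong in the TGF-β1 list only. Strong peaks began at a height of 15 in that list and of 17 in the control list. The control peak of SLC16A3 and the TGF-β1 peak of ALDOA were at 15. Strong in the control list only were GPI (22 and 14), ENO1 (17 and 12) and, chosen after their values were seen, PDK1 (35 and 8), TPI1 (24 and 9) and PFKFB4 (17 and 11). The control peak of TPI1 lay at the higher-coordinate end of the gene and its highest TGF-β1 gene-end peak at the lower. Another TGF-β1 peak, whose height was not examined here, overlapped that control peak. HK1 (13 and 13), the first enzyme of the pathway, and LDHB (14 and 11) were strong in neither. Strong peaks were thus found at 6 and 4 glycolysis genes, and 26.0% and 57.1% of random lists had as many.

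A gene-end peak of any height was found for 24 and 23 of 25 genes of TGF-β signalling in the control and TGF-β1 lists, with 0.65% and 2.85% of random lists as high. Of these 25 genes, 12 had a strong peak in the control list and 10 in the TGF-β1 list, 9 of them in both. As many were found in 0.04% and 0.32% of random lists. JUNB, an AP-1 subunit, had heights of 98 and 120 from a peak it shared with HOOK2. SMAD2, a signal transducer of the pathway, had 53 and 49, and ID1 had 24 and 39. PMEPA1, an inhibitor of the pathway, had 54 and 32, and CCN2, connective tissue growth factor, 22 and 14. TGFB1 itself had a low peak of 8 and 9, shared with B9D2.

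The genes of extracellular matrix and fibrosis did not stand out. A gene-end peak was found for 17 and 20 of 23, with 78.3% and 19.6% of random lists as high, and strong peaks at 3 in each list, with 80.8% and 77.2% of random lists as high. CCN1, a matricellular protein, had heights of 43 and 45, and a peak shared by LOXL2, a collagen cross-linking enzyme, and R3HCC1 had 26 and 22. ACTA2, smooth muscle actin, had 23 and 13, and THBS1, thrombospondin 1, had a gene-end peak of 16 in the TGF-β1 list only, although a control peak beyond the window overlapped it. FN1, fibronectin, had 9 and 13, and COL1A1, a chain of type I collagen, 12 and 7. Of the epithelial to mesenchymal transition list, 13 and 12 of 16 genes had a gene-end peak, with 40.0% and 60.1% of random lists as high, and 3 and 4 a strong peak, with 49.8% and 21.9% of random lists as high. The keratin genes KRT18 and KRT8 shared a peak of 89 and 71, TJP1 of the tight junction had 21 and 19, and SNAI1, a repressor of epithelial genes, 16 and 17. VIM had 11 and 8 and CDH2 5 and 7, in both genes at places that did not overlap, and CDH1, the epithelial cadherin, had no gene-end peak.

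Autophagy genes had the highest share of strong peaks of the 15 lists, 12 of 18 in the control list and 11 in the TGF-β1 list, with 10 in both. Of 10000 random lists, matched on gene length only, 0 had as many in either list. Gene-end peaks of any height were found at 17 and 18 of these genes, with 9.07% and 1.31% of random lists as high. WIPI1, a phosphoinositide-binding autophagy protein, had heights of 140 and 180, WIPI2 71 and 51, and GABARAPL1, an ATG8 family member, 67 and 48. ULK1, the kinase that starts autophagy, had 67 and 15 at places that did not overlap. Another TGF-β1 peak, whose height was not examined here, overlapped the ULK1 control peak, so that site was not in the control list only. MAP1LC3B had 17 and 21 from a peak it shared with FBXO31. Of the hypoxia response list, 8 of 14 genes were strong in the control list and 4 in the TGF-β1 list, with 0.03% and 17.3% of random lists as high. With peaks of any height the order was the other way round, 13 and 14 genes, with 9.49% and 1.54% of random lists as high. ANKRD37, with its neighbour LRP2BP, had 147 and 99, BNIP3L, a mitophagy receptor, 88 and 64, DDIT4, an inhibitor of mTORC1, 40 and 25, and NDRG1 25 and 31. Strong in the control list only, and chosen after their values were seen, were HIF1A (24 and 12), EGLN1 (23 and 14), ARNT (19 and 13) and EPAS1 (18 and 13). The difference between the lists was not tested.

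**Figure D2:**
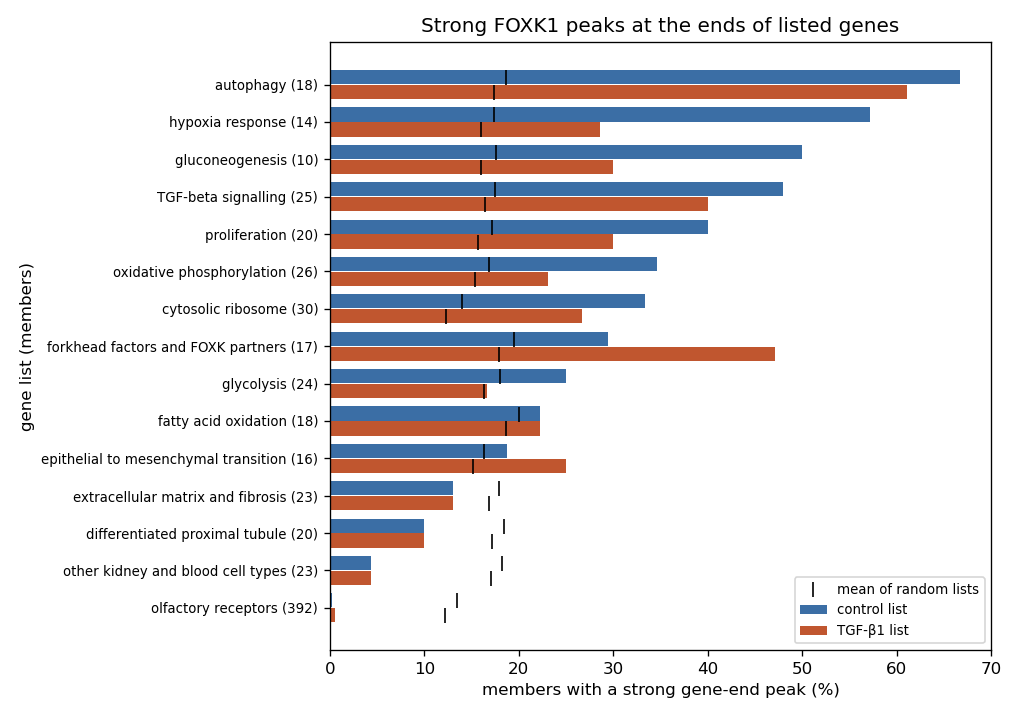
Percent of the members of each gene list with a strong gene-end peak (x axis) in the control and TGF-β1 lists, with the number of members in brackets (y axis); black ticks are the means of 10000 random lists matched on gene length. Autophagy genes had 12 and 11 strong members of 18, and olfactory receptors 1 and 2 of 392.

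Among the metabolic lists, gluconeogenesis had strong peaks at 5 and 3 of 10 genes, with 1.89% and 20.3% of random lists as high, and peaks of any height at 9 and 8, with 28.8% and 55.8%. GOT1, the cytosolic aspartate aminotransferase, had heights of 171 and 192, G6PC3 25 and 25, PC, pyruvate carboxylase, 19 and 18, and PCK2 23 and 8. Fatty acid oxidation had strong peaks at 4 and 4 of 18, with 50.3% and 43.5% of random lists as high, and peaks of any height at 16 and 18, with 29.7% and 1.92%. HADH had 26 and 21, ETFDH 32 and 19, and HADHA and HADHB, both subunits of the trifunctional protein, shared a peak of 12 and 18. Oxidative phosphorylation had strong peaks at 9 and 6 of 26, with 2.19% and 19.7% of random lists as high, and peaks of any height at 25 and 23, with 0.38% and 5.31%. COX4I1, a cytochrome c oxidase subunit, had 42 and 32, ATP5F1B 44 and 23, and NDUFB5 28 and 20. The peaks of ETFDH, COX4I1, ATP5F1B and NDUFB5 were shared with the neighbouring genes C4orf46, EMC8, BAZ2A and MRPL47.

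Proliferation genes were strong at 8 and 6 of 20, with 1.40% and 7.79% of random lists as high, and had peaks of any height at 20 and 19, with 0.42% and 2.97%. MCM2, with its neighbour TPRA1, had heights of 97 and 74, MYC 41 and 37, and CCNE1, cyclin E1, 37 and 39. Cytosolic ribosome genes all had a gene-end peak in both lists, 30 of 30, which 0 of 10000 random lists matched, and 10 and 8 were strong, with 0.66% and 2.27% of random lists as high. RPS14 had 37 and 31, RPL27 33 and 22, and RPL4, with its neighbour ZWILCH, 24 and 20. The list of forkhead factors and FOXK partners had 5 and 8 strong members of 17, with 22.4% and 0.55% of random lists as high. With peaks of any height the order was the other way round, 17 and 16 members, with 1.94% and 11.05% of random lists as high. FOXO3, a forkhead factor, had 21 and 64, OGT, the O-GlcNAc transferase, 29 and 30, YY1 20 and 33, and MBD6 8 and 44. Both MBD6 peaks also lay at the end of DDIT3, a stress-induced transcription factor. The control and TGF-β1 peaks given for FOXO3 and for MBD6 lay at places that did not overlap. Both TGF-β1 peaks were overlapped by another control peak, whose height was not examined here. They are therefore not sites of the TGF-β1 list only. FOXK2 had 16 and 16 and, chosen after its values were seen, FOXO1 had 16 and 15, and both were strong in the TGF-β1 list only because strong peaks began at a height of 15 there and of 17 in the control list. The difference between the lists was not tested. FOXK1 itself had a gene-end peak of 7 in the control list only.

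Of 20 genes of the differentiated proximal tubule, 10 had a gene-end peak in each list, and 0.44% and 0.50% of random lists had as few. The amino acid transporter gene SLC3A1 had heights of 56 and 24 and SLC13A3, a dicarboxylate transporter, 27 and 26, the 2 strong members in each list. Of 23 markers of other kidney and blood cells, 11 and 15 had a peak, and 0.13% and 14.5% of random lists had as few. The 1 strong member was CD68, with 42 and 35, and its peak was shared with EIF4A1, a translation initiation factor. Of 392 olfactory receptor genes, which are silent in most tissues, 133 and 138 had a peak, against 252 and 249 in random lists.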

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

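The tests of list-only peaks and of chromosomes were all chosen after the results were seen. Peaks on unplaced contigs, which no comparison used, numbered 394 in the control list and 506 in the TGF-β1 list. On the contig GL000220.1 the median height was 49.5 in the control list and 39 in the TGF-β1 list, and on KI270733.1 it was 51 and 47, against a median of 5 in each whole list.

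Most peaks of either list had no counterpart in the other, 73.9% of control and 77.1% of TGF-β1 peaks. Gain of sites of height 20 or more after TGF-β1 cannot be the main cause by number alone. Only 5779 of the 439136 TGF-β1 peaks were that high, and 306 of them were among the 338728 without a counterpart. This follows from the height minimum and is not a test of gain. Of all peaks that high, 3.94% of control and 5.30% of TGF-β1 peaks had no counterpart, a difference of 1.35 points (95% interval 0.63 to 2.08). That comparison does not decide whether some strong sites were gained. TGF-β1 peaks under height 10 without a counterpart lay at gene ends in 2.33% of cases (2.28 to 2.38), against 2.46% by random placement. Those with a counterpart did so in 8.23%. As a set, the peaks without a counterpart were thus not enriched at gene ends. This does not exclude gain of weak sites there, because noise peaks could hide it and places with a control peak were left out by selection. Counting noise near the calling threshold remains a candidate explanation, since overlap rose with height in both lists. Weak sites gained at gene ends or away from them stay open, because no replicate library was there to test them.

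The ratio of TGF-β1 to control peaks differed between the 23 chromosomes compared, with Y left out, from 0.90 on X to 1.38 on chromosome 4. A different copy number of chromosomes in the 2 cultures is argued against by strong peaks, whose ratio ran from 0.96 to 1.14 and did not follow the list size ratio across 23 chromosomes (Spearman's rho -0.16). The ratio rose with the mean height of control peaks below 20 (rho 0.78, Pearson's r 0.68, and without chromosomes 20 and X rho was 0.74 and r 0.69), a measure taken from the same control peaks as the ratio, and less closely with the mean height of TGF-β1 peaks below 20 (rho 0.55, r 0.51). Low peaks gained where reads are dense, at another depth or threshold, may explain part of it. Chromosomes are not independent replicates, and an effect of TGF-β1 on weak binding was not tested.

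Of the peaks of height 20 or more without a counterpart, 300 in the control list and 306 in the TGF-β1 list, 76.0% and 87.6% lay outside annotated genes. Of those TGF-β1 peaks, 4 (1.31%, 0.36 to 3.31) lay at gene ends, against 22.8% of peaks with a counterpart. This argues against many strong sites gained at gene ends where the control list had no peak. It does not exclude strong sites gained over a low control peak, because places with any control peak were left out by selection. In 1 Mb bins without a protein-coding gene lay 67.0% of the control peaks and 69.3% of the TGF-β1 peaks without a counterpart, against 2.15% and 2.28% of peaks with a counterpart. Reads of repeated sequence piling up in gene-free blocks may explain most of them, although repeat content itself was not analysed here. Gain or loss of FOXK1 in such blocks stays open.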

How the results depend on the processing

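Alternatives by height, strong peaks, a 500 bp window and 5 kb around the gene were chosen after seeing the data, the others before. Merging peaks within 500 bp kept both list sizes within 1.5 times, and so did the 500 bp window for all genes with a gene-end peak, those in 1 list only and glycolysis, the counts it was run on, and 5 kb around the gene for glycolysis. Heights of at least 10 left 36862 control and 29466 TGF-β1 peaks and of at least 20 left 7609 and 5779, which turned the order of the lists. An overlap of 50% of both peaks lowered the shared percent to 13.0% of control and 11.3% of TGF-β1 peaks, while it was 65.4% and 63.9% among strong peaks, 82.8% and 84.7% at height 10 or more and 96.1% and 94.7% at 20 or more. The percent at gene ends was 14.6% and 13.6% with a 5 kb window, 18.8% and 18.6% at height 10 or more and 24.2% and 21.6% at 20 or more. Genes with a gene-end peak fell to 3412 and 3145 with strong peaks and to 7982 and 6550 at height 10 or more. Genes in 1 list only fell to 1022 in control and 755 in TGF-β1 with strong peaks. With a gene-end peak of height 10 or more in 1 list and no gene-end peak in the other they were 190 and 102, and with 20 or more 11 and 9. For 35 and 22 of the former and 4 and 6 of the latter, all these peaks were overlapped by a peak of the other list that missed the window. Glycolysis genes with a peak fell to 14 and 11 at height 10 or more and to 6 and 4 with strong peaks. Unmatched random lists were as high as glycolysis in 4.04% (control) and 3.43% (TGF-β1). Higher minimums leave fewer peaks, which accounts for the lower counts; the cause of the other shifts was not tested. Unknown depth limits every comparison of the list sizes. No paired analysis was possible because each condition had 1 FOXK1 library. Settings fixed beforehand that needed fold enrichment, q values, strand or sequence were not run.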

Other observations

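The gene families below were chosen after the results were seen, and 12 were looked at. Replication-dependent histone genes, 55 on chromosome 6, 13 on chromosome 1 and 1 on chromosome 12, had strong gene-end peaks at 26 of 69 in the control list and 24 in the TGF-β1 list, 18 of them in both, against 6.53 and 5.97 in random lists. Neighbouring genes shared peaks, and 19 and 16 separate peaks gave these counts. Genes of the mitochondrial ribosome were strong at 27 and 21 of 77, against 12.02 and 10.9 in random lists. Collagen genes were strong at 2 and 1 of 44, against 7.88 and 7.35, and keratin genes at 2 and 3 of 55, against 8.39 and 7.39. Zinc finger genes were strong at 69 and 71 of 477, against 87.9 and 80.3, with 1.01% and 13.6% of random lists as low, but had a gene-end peak of any height at 408 and 394, against 374.6 and 368.9. Solute carriers were strong at 51 and 47 of 347, against 64.0 and 59.2. For the proteasome the counts were 11 and 9 of 39, against 6.58 and 6.02, for the MCM helicase 4 and 5 of 9, against 1.79 and 1.65, and for cyclins 5 and 5 of 15, against 2.63 and 2.42. For KLHL genes they were 7 and 8 of 37, against 6.74 and 6.29, for EXOSC genes 3 and 2 of 10, against 1.69 and 1.54, and for TBC1D genes 7 and 7 of 43, against 7.68 and 7.18.

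Genes of some small RNAs carried strong peaks as well. Of 443 tRNA genes, 17.4% in the control list and 16.03% in the TGF-β1 list had a strong peak within 1 kb, against 1.53% and 1.45% by random placement, from 53 and 45 separate peaks. Of 154 snRNA genes, whose products build the spliceosome, 22.1% and 23.4% had a strong peak, against 1.56% and 1.63%. The shares were far lower for 1199 snoRNA genes, 2.25% and 3.09% against 1.17% and 1.24%, and for 1913 miRNA genes, 4.13% and 3.76% against 1.23% in each list.

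Peaks of height 500 or more numbered 3 in the control list and 8 in the TGF-β1 list, and each was at least 402 kb from a protein-coding gene. The highest in both lists was on chromosome 3, from 93470370 to 93470787 in the TGF-β1 list with a height of 8140, and with 4805 in the control list. A TGF-β1 peak of 7187 on chromosome 1, from 125180054 to 125180395, had no control peak across it.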
